A study of Mus musculus with 12 samples.

How the data were processed

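RNA from mouse cornea was sequenced in 4 groups: untreated controls, a dry eye disease (DED) model, DED mice given stem cell-derived exosomes as an eye drop, and DED mice given the exosomes intravenously. Exosomes are small membrane vesicles released by cells. The labels list 3 samples per group, all with the same date, and give no sex, age or time of day of collection. They list no DED mice given a drop or an injection without exosomes. An effect of the exosomes therefore cannot be told apart from one of the drop, the injection or the handling. The deposited table holds log2 values for 28548 lines named by gene symbol, in 1 column per sample. In 11 of the columns, 2 to the power of the value minus 1 was a whole number within 0.01 for 99.9748% of the values, so the unit in the deposited table is log2 of the whole count plus 1. These values were not normalized between samples, although the table carries the word normalize in its name. The name also carries what reads as a time in hours, which the sample titles do not explain. The deposited column of the third eye drop sample was not such a library. Its log2 value equalled the mean of the other 2 eye drop columns for all 28548 lines, with a largest distance of 5e-09, and 26.9721% of its values were whole on the count scale. It was left out, so the eye drop group has 2 independent samples and the fit has 11. The authors' processing notes give the genome build as mm9; the aligner, the counting tool and the annotation are not given in the sources used here.

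Counts were recovered by rounding. The 10 lines whose values were not whole, with values averaged over repeated symbols, and 9 lines named by a date were left out, 19 in all, with at most 0.049% of a library's counts. A further 534 lines were at 0 in all 11 samples. Gene positions are not given, because the deposited table holds symbols alone. A GENCODE annotation of the later build GRCm38 served for transcript length, GC content and the overlap of Krt12 with an antisense gene. Length and GC content were matched for 21124 of the 21203 genes tested (99.6%).

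Library totals ran from 8956553 to 14263045 counts. Each library was divided by a median-of-ratios size factor, computed over genes with a count in every sample, and log2(normalized count + 1) was used. Genes with a normalized count of at least 1 in at least 3 samples were kept. One linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and robust estimation, on 7 residual and a median of 9.59 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over the 21203 genes within each of 6 comparisons, with a threshold of 0.05. They measure the spread between these samples alone. The 1060 genes that chance would give at an unadjusted p under 0.05 are a mean. Its spread, which is wider where genes are correlated, was not computed, so an excess over it was not tested. The 44 gene lists, of pathways and of cell types that a corneal dissection could hold, had 6 or more measured members. They were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with the correlation estimated from the data. Lists are said to pass, rise or fall by the first test, which takes their genes as nearly independent. Within groups, retina, lens and muscle markers had a mean pairwise correlation of 0.77, 0.81 and 0.81, far above 0.01. Their p-values at the preset correlation are therefore too small. Only the cholesterol synthesis list passed with an estimated correlation, in each treated group against the DED model. Il36a was found under the older symbol Il1f6, Il36g under Il1f9 and Muc21 under Gm9573. A group mean or difference is given in normalized counts with its SD and n, or as a log2 fold change with its standard error (SE).

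The lists, the comparisons, the named gene rule and most alternatives were chosen before the data were examined. The plan foresaw 12 samples and either counts or normalized values. The table held log2 values, so the plan's limma test, the one for normalized values, was used, although these values were not normalized between samples. The plan's test for counts was not run on the recovered counts, so how far the calls depend on this choice was not measured. The choice of test, the size factors and the use of 11 samples were made after the unit had been determined. Genes were named by rule: up to 8 higher and 8 lower genes with the smallest p among those past the threshold with a log2 fold change of at least 1 in size, predicted genes left out, and up to 4 members of each list with the smallest p. Some genes that the rule names are not reported here. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. Where a group was at 0 in all its libraries, the fold is a lower bound against a floor of 3 normalized counts per library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

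The alternatives were quantile normalization, 75th percentile scaling, other filters (none, a mean of 5), a pseudocount of 0.1, limma without trend and robust estimation, only the 2 groups compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. Added after the data were seen were library totals, the values as deposited without scaling, a filter of 10 counts, voom weights, thinning to the lowest total, removal of each library's trend with length and GC content, the third eye drop column, and leaving out the 3 libraries highest in retina, lens and muscle markers. The movement of DED genes after treatment and the overlap of the routes were set against 100 simulations without a treatment effect, because both contrasts share the DED samples. Added after the results were seen were simulations with the difference of DED and control scaled down until about as many genes were called, with noise independent between genes or built from the residuals so that genes kept their correlation.

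The pipeline was tested on simulated data with the group sizes used here, 10 simulations per comparison, each with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 49.5% of the 2-fold and 87.1% of the 4-fold changes for the DED model against control, 34.2% and 83.9% for eye drop against the DED model, 48% and 88.9% for intravenous against the DED model, and 37.6% and 84% for intravenous against eye drop. The share of calls that were false was 6.8%, 5.5%, 6.8% and 7.2%, above the nominal 5%. The changed genes were drawn from those with a mean of at least 10 normalized counts, so recovery of lower genes was not measured. The noise was independent between genes, so these shares do not cover correlated genes.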

Results

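The corneal RNA-seq data comprised 11 independent libraries: 3 from untreated control mice, 3 from the DED model, 2 from DED mice given exosome eye drops and 3 from DED mice given exosomes intravenously. Total counts were 10893978 to 12972945 in controls, 10355125 to 14263045 in the DED model, 12571461 to 13687074 with the eye drop and 8956553 to 9501661 with the intravenous route. Krt12, the keratin typical of the corneal epithelium, took 2.75% to 4.50% of a library's counts. On the build GRCm38, Krt12 lies on the minus strand of chromosome 11 from 99415666 to 99422259 and overlaps the antisense gene A830036E02Rik (99416956 to 99425497), so the counts of both are uncertain. The first 3 principal components held 25.4%, 14.7% and 12.5% of the variance. Single libraries stood apart on them: control 1 was lowest on the first (-98, the other controls at -25.8 and -55.4), and intravenous 3 was lowest on the third (-101.6, intravenous 1 and 2 at 16.4 and 19). Highest on the first were intravenous 1 (72.2) and DED 3 (64.9), the libraries highest in muscle and in retina markers. On the second DED 3 was lowest (-75.8) and intravenous 2 highest (69.6). The chi-square per gene between libraries was 51.17 and 66.8 between intravenous 3 and intravenous 1 and 2, and 8.35 between those 2. A test of any difference between the 4 groups found 956 of 21203 genes changed at an adjusted p of 0.05. That count was 210, 214, 628 and 402 without control 1, control 3, DED 2 and DED 3, 424 and 497 without eye drop 1 and 2, and 344, 420 and 3749 without intravenous 1, 2 and 3. It was 33 with limma without trend and robust estimation, 84 without the 3 libraries highest in retina, lens and muscle markers, 2246 with the third eye drop column, 2101 with library totals and 5137 as deposited.

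The first comparison asked how the cornea of the DED model differed from that of untreated mice. Genes of the circadian clock and its output gave many of the strongest differences. Dbp, a transcription factor driven by the clock, fell from 1499 ± 254 normalized counts in control (SD, n = 3) to 229.9 ± 107 in the DED model (SD, n = 3), a log2 fold change of -2.82 (SE 0.30, adjusted p = 0.00057). Its relative Tef fell by 1.87 on the log2 scale (SE 0.21), the period gene Per3 by 1.77 (SE 0.19), and the repressors Nr1d1 and Nr1d2 by 1.75 (SE 0.24) and 1.76 (SE 0.20). Arntl, the activator of the clock (also called Bmal1), rose by 1.42 (SE 0.22, adjusted p = 0.00409), and Cry1, a repressor, rose by 1.40 (SE 0.20, adjusted p = 0.00225). Of the 18 measured clock list genes, 8 fell and 2 rose over all genes, and 11 fell and 4 rose adjusted over the list alone. Adjusted p-values of lists are given in pairs, the first with the set correlation of 0.01 and the second with the correlation estimated from the data. The clock list fell with a median of -0.96 (adjusted p = 2.67e-07 and 0.146).

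**Figure D1:**
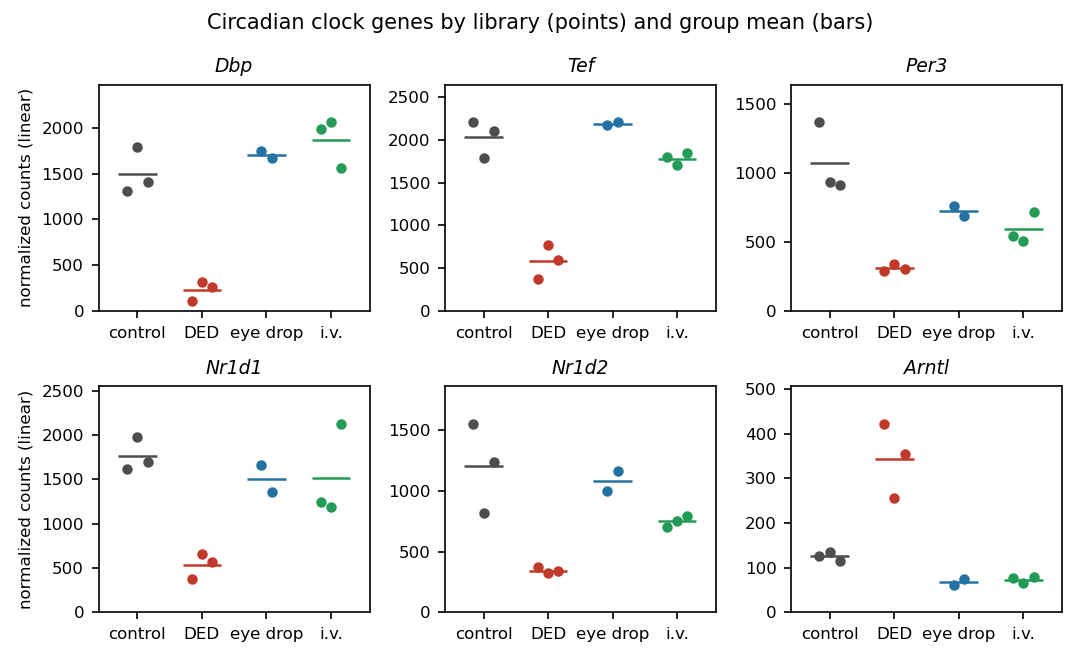
Normalized counts (y axis, linear from 0) of Dbp, Tef, Per3, Nr1d1, Nr1d2 and Arntl in each library, by group on the x axis; points are libraries and bars are group means. In all 3 DED libraries the first 5 genes lie below every control library and Arntl lies above, and the libraries of both treated groups lie on the control side of the DED libraries for each of the 6 genes. All treated libraries also lie below every control library for Arntl (60.5 to 78.4 against 114.3 to 136.2). The same holds for Per3 (506.2 to 760.8 against 914 to 1364.9). For the other genes some treated libraries lie within the control range.

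Inflammatory, cornification and cholesterol synthesis genes were higher in the DED model. Sprr1a, a precursor of the cornified envelope of squamous epithelia, rose from 179 ± 80.2 to 2815 ± 1740 normalized counts (SD, n = 3 each; log2 fold change 3.93, SE 0.49). The interleukin-36 genes Il1f6, Il1f8 and Il1f9 rose by 2.80 (SE 0.38), 2.16 (SE 0.26) and 2.20 (SE 0.27) on the log2 scale. Fabp5, a fatty acid carrier, rose by 1.77 (SE 0.24), the antimicrobial protein gene Ltf by 1.83 (SE 0.27), and Pmvk, an enzyme of the mevalonate pathway, by 1.32 (SE 0.18). Inflammatory cytokine genes rose as a list (25 genes, median 0.93, 0.87 with genes at 0 in a group set to their bound, adjusted p = 1.98e-09 and 0.146). Of these, 4 rose over all genes and 14 adjusted over the list alone. Squamous cornification (30 genes, median 1.10, 1.03 with bounds, adjusted p = 3.18e-09 and 0.146) had 3 members that rose over all genes, and 12 that rose and 1 that fell adjusted over the list alone. Antimicrobial peptides and alarmins (15 genes, median 1.52, adjusted p = 1.13e-05 and 0.146) had 3 risers over all genes and 9 adjusted over the list alone, and a median of 0.82 without DED 1. Cholesterol synthesis genes rose (24 genes, median 0.52, adjusted p = 4.72e-08 and 0.0624). Over all genes 6 of them rose, among them Insig1 (1.03, SE 0.19), Fdps (0.95, SE 0.18) and Idi1 (1.05, SE 0.21). Adjusted over the list alone 12 rose. Fatty acid and lipid metabolism did not pass as a list (31 genes, median 0.09, adjusted p = 0.945). Fabp5 and the desaturase Scd1 (1.06, SE 0.18) rose in it. Another 3 genes fell over all genes, the lipoxygenases Alox15 (-1.62, SE 0.31) and Alox12e (-2.22, SE 0.39) among them. In all 6 rose and 3 fell adjusted over the list alone.

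**Figure D2:**
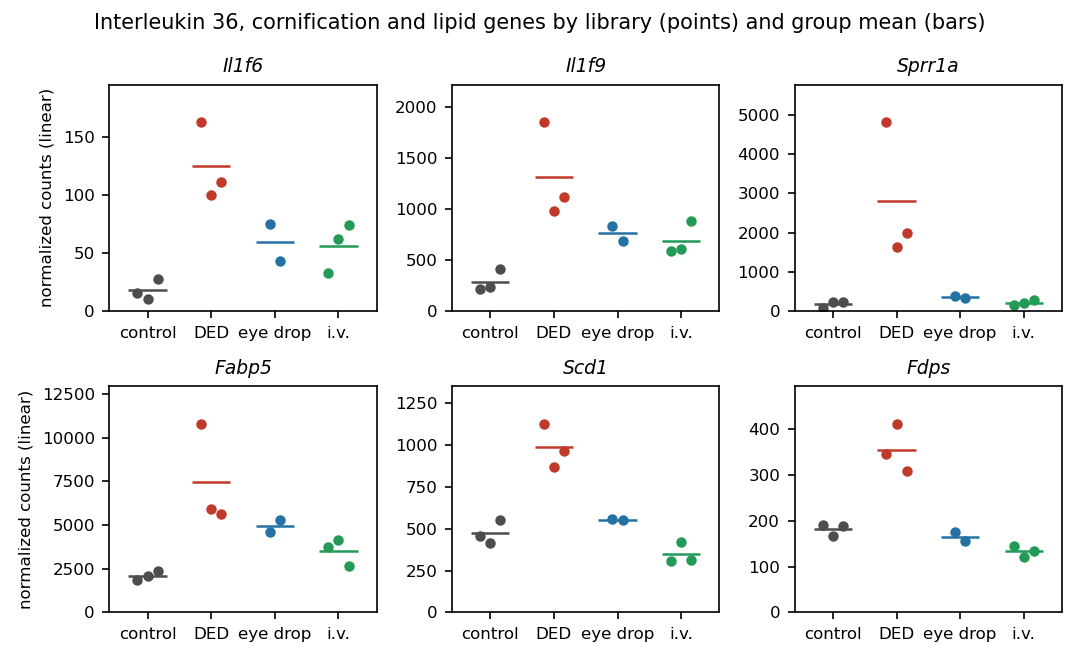
Normalized counts (y axis, linear from 0) of the interleukin-36 genes Il1f6 and Il1f9, the cornified envelope gene Sprr1a and the lipid genes Fabp5, Scd1 and Fdps in each library, by group on the x axis; points are libraries and bars are group means. All 3 DED libraries lie above the 3 controls for each gene, and Sprr1a averaged 2815 in the DED model against 213 with intravenous exosomes.

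Further genes among the strongest were Pigz, an enzyme of membrane anchor synthesis (15.4 ± 4.47 to 219 ± 46.3 normalized counts, SD, n = 3 each; log2 fold change 3.76, SE 0.31), Asb2, a subunit of a ubiquitin ligase (3.48, SE 0.43), Gch1 (1.82, SE 0.23), AA467197 (1.80, SE 0.23), Ifitm1 (1.46, SE 0.18) and Las1l (1.25, SE 0.16). All of these rose. Those that fell included Cyp2a5, a cytochrome P450 whose near-identical relative Cyp2a4 makes its count uncertain (-1.94, SE 0.22), the cell cycle regulator Ccnd2 (-1.57, SE 0.18), Gldc (-1.21, SE 0.17) and the neurotrophin receptor gene Ngfr (-1.37, SE 0.21, adjusted p = 0.00409). Ngfr was the 1 member of 22 neurotrophic and nerve genes to change over all genes or adjusted over the list alone. It went against the direction of the list, which rose (median 0.72, 0.48 with bounds; adjusted p = 0.00951 and 0.417). WNT and NOTCH genes fell (28 genes, median -0.33, adjusted p = 0.00275 and 0.278). Over all genes Notch1 fell by 1.00 (SE 0.21), Jag1 by 0.96 (SE 0.21) and Jag2 by 1.07 (SE 0.20), with 7 falling and 1 rising adjusted over the list alone. Oxidative phosphorylation (47 genes, median 0.38, adjusted p = 1.98e-09 and 0.446), cytosolic ribosomal proteins (50 genes, 0.38, 1.13e-06 and 0.554), glycolysis and hypoxia (29 genes, 0.43, 7.34e-06 and 0.151) and the unfolded protein response (22 genes, 0.14, 0.0419 and 0.435) rose. Over all genes 2, 0, 1 and 0 of their members rose, and 3, 0, 6 and 6 adjusted over the list alone. Ndufa4 (1.24, SE 0.19) and the ribosomal protein genes have processed pseudogenes, so their counts are uncertain. Across genes, which are not independent replicates, the change fell with transcript length (rank correlation -0.45), from a median of 0.18 in the shortest to -0.25 in the longest of 3 equal length groups.

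Lists of the stroma, vessels and inner eye were higher too, and they moved beside markers of retina and lens. Collagens and stromal matrix rose (28 genes, median 1.32, adjusted p = 3.9e-09 and 0.383). No member passed over all genes, with 16 rising and 1 falling adjusted over the list alone. TGF-beta and EMT genes rose (26 genes, 0.93, 0.000107 and 0.259). Acta2, smooth muscle actin (2.04, SE 0.35), and Tgfb3 (1.94, SE 0.41) rose over all genes, with 10 rising and 2 falling adjusted over the list alone. Matrix metalloproteinases (18 genes, 1.09, 7.49e-05 and 0.151) included Mmp3 (2.34, SE 0.47) over all genes and 5 risers adjusted over the list alone. Keratocyte markers (18 genes, 0.91, 0.00142 and 0.487), corneal endothelium markers (13 genes, 2.45, 0.000316 and 0.264), vessel markers (16 genes, 1.30, 4.63e-05 and 0.264), neutrophil markers (9 genes, 0.94, 0.00142 and 0.146) and iris, ciliary body and melanocyte markers (17 genes, 2.03, 1.49 with bounds, 2.44e-05 and 0.351) rose. In that order 0, 1, 1, 1 and 2 members rose over all genes, and 0, 4, 7, 4 and 7 adjusted over the list alone, where 1 iris gene fell. The neutrophil gene that rose over all genes was Ltf, which is also in the antimicrobial and lacrimal gland lists. The neutrophil list lay near the floor, with medians of 0.80, 1.96 and 1.52 (log2 of the normalized count plus 1) in controls 1, 2 and 3. Other lists that rose were also low in these controls. Metalloproteinases were at 2.22, 3.31 and 2.98, vessel markers at 2.22, 3.48 and 2.62, and neurotrophic genes at 2.07, 3.35 and 2.80. Retina markers rose (24 genes, 2.33, 5.27e-08 and 0.435) and lens markers fell (23 genes, -1.86, 0.00142 and 0.579), with no member passing either way. Without control 1 the medians were 0.61 for matrix metalloproteinases, 1.33 for retina and 1.28 for iris markers. Without DED 3 they were 0.58 for keratocyte, 1.49 for endothelium and 1.52 for retina markers, and without DED 1 1.43 for keratocyte markers. Neurotrophic genes were at 1.09 without control 2 and 1.16 without DED 1. Lens markers lost their call without control 3 (-0.77, adjusted p = 0.184), WNT and NOTCH without DED 1 (-0.20, adjusted p = 0.121), and neurotrophic genes without DED 3 (0.55, adjusted p = 0.0533). The unfolded protein response lost it without control 1 (0.14, adjusted p = 0.0693), control 2 (0.22, adjusted p = 0.0542) or DED 2 (0.13, adjusted p = 0.124), with library totals (0.03, adjusted p = 0.11) and as deposited (0.10, adjusted p = 0.0582).

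Between the DED model and control 265 genes changed, 156 higher and 109 lower (58.9% higher), and 191 of them by at least 2-fold, where 3700 genes had an unadjusted p under 0.05 and chance would give 1060. The share of higher genes among those called was 69.2% of 286 with 75th percentile scaling, 41.1% of 333 with library totals and 74.2% of 178 as deposited. Of the 44 lists 21 passed, 18 higher and 3 lower, none with an estimated correlation and 11 with the rotation test fry, which asks whether a list's genes moved one way on balance. The count fell to 51 without control 1, 95 without control 3, 115 without DED 2 and 74 without DED 3, to 63 without the 3 libraries highest in retina, lens and muscle markers and to 60 with limma without trend. It rose to 594 with the third eye drop column and 662 with only the 2 groups. Of the 54 named genes, 23 kept their call without each library: Pigz, Ifitm1, Il1f6, Il1f8, Il1f9, Asb2, Gch1, AA467197, Las1l, Ltf, Sprr1a, Ndufa4, Pmvk, Fabp5, Per3, Cyp2a5, Nr1d1, Nr1d2, Tef, Ccnd2, Dbp, Gldc and Ngfr.

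The next comparison asked how the cornea of DED mice given the exosome eye drop differed from that of the DED model. The clock genes stood opposite to their DED change. Dbp rose to 1704 ± 55.4 normalized counts (SD, n = 2) from 229.9 ± 107 in the DED model (SD, n = 3), a log2 fold change of 3.01 (SE 0.33, adjusted p = 0.00193), and Tef (1.98, SE 0.24) and Nr1d2 (1.65, SE 0.22) rose with it. Arntl fell to 68 ± 10.6 from 344 ± 84 (-2.30, SE 0.25, adjusted p = 0.000597). Nfil3, a repressor that opposes Dbp, was at 0 in both eye drop libraries, at least 6.98-fold lower than in the DED model. Of 18 clock genes 5 rose and 2 fell over all genes, and 10 rose and 4 fell adjusted over the list alone. The list rose (median 0.93, adjusted p = 2.45e-07 and 0.315). Cyp2a5 rose by 2.57 (SE 0.25, adjusted p = 0.000216), Ccnd2 by 1.57 (SE 0.20), the death ligand gene Tnfsf10 by 2.62 (SE 0.38). The lipoxygenases Alox15 and Alox12e rose by 2.53 (SE 0.35) and 3.27 (SE 0.43). Pigz (-2.14, SE 0.34), Asb2 (-2.90, SE 0.48), Slc46a2 (-1.38, SE 0.24) and the histone gene Hist1h1c, one of a family of similar genes (-1.35, SE 0.25), fell. C2cd4b was at 0 in both libraries, at least 5.7-fold lower.

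Cholesterol synthesis genes fell with the eye drop (24 genes, median -0.35, adjusted p = 5.91e-10) and also passed with an estimated correlation (adjusted p = 0.0317). Fdps, the farnesyl diphosphate synthase, fell over all genes (-1.09, SE 0.20, adjusted p = 0.0358), and 7 fell adjusted over the list alone. Squamous cornification fell (30 genes, -0.99, 1.3e-07 and 0.315), as did inflammatory cytokines (25 genes, -0.47, 0.000284 and 0.444) and the unfolded protein response (22 genes, -0.31, 0.000284 and 0.346). No member of these lists passed over all genes, and 4, 1 and 1 fell adjusted over the list alone. Interferon genes rose (38 genes, 0.75, 2.61e-11 and 0.502). Gbp2, a guanylate-binding protein gene (1.26, SE 0.18, adjusted p = 0.00566), was the single riser over all genes and adjusted over the list alone. MHC class I genes rose (17 genes, 0.25, 0.00207 and 0.692), 0 over all genes and 2 adjusted over the list alone. Ctss, the protease cathepsin S, rose (1.31, SE 0.21, adjusted p = 0.0117) in the MHC class II list, which did not pass (9 genes, 0.11, adjusted p = 0.158). Cell cycle (40 genes, -0.27, 0.00943 and 0.729) and glycolysis genes (29 genes, -0.19, 0.0026 and 0.444) fell. No member passed over all genes, with 0 and 3 falling adjusted over the list alone. Lens markers rose (23 genes, 6.33, 3.02e-27 and 0.315), 1 over all genes (Lim2, 6.35, SE 1.14) and 16 adjusted over the list alone. Lim2 had 51.5 and 190.8 normalized counts in the eye drop libraries and 0, 0 and 0.9 in the DED libraries. Retina markers fell (24 genes, -2.69, 4.83e-13 and 0.444), 0 over all genes and 1 adjusted over the list alone. The lens crystallin gene Cryaa had 800.5 and 10206 normalized counts in the eye drop libraries and 13.7, 103 and 14 in the DED libraries. Cryab, another crystallin gene that other tissues also express, rose as well (1.32, SE 0.26). Without eye drop 2 cornification was at -0.59 and the cell cycle at -0.49. Without eye drop 1 the unfolded protein response was at -0.15 and retina markers at -1.62, and glycolysis was at -0.34 without DED 1. MHC class I lost its call without DED 1 (0.10, adjusted p = 0.105), cell cycle without DED 1 (-0.14, adjusted p = 0.482) or eye drop 1 (-0.06, adjusted p = 0.985) and as deposited (-0.21, adjusted p = 0.077). Glycolysis lost it without eye drop 2 (-0.14, adjusted p = 0.0668) and without the 3 libraries highest in neighbouring tissue markers (-0.13, adjusted p = 0.216). The collagen list, which did not pass (28 genes, -0.28, adjusted p = 0.265), fell to -1.02 without eye drop 1 (adjusted p = 3.56e-12) and rose to 0.54 without eye drop 2 (adjusted p = 0.000176).

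With the eye drop 1495 genes had an unadjusted p under 0.05 against the DED model, where chance would give 1060 on average. After adjustment 41 genes changed, 27 higher and 14 lower, 40 of them by at least 2-fold. The count was 15, 21 and 18 without DED 1, 2 and 3, and 6 and 4 without eye drop 1 and 2, where the lone eye drop library was assumed to vary like the other groups. It was 6 with limma without trend, 26 with the replicate number as a block, 115 with the third eye drop column and 0 without the 3 libraries highest in neighbouring tissue markers, which leaves 1 eye drop library. Of the 44 lists 11 passed (17 without DED 2, 21 without eye drop 1 and 17 without eye drop 2), 1 with an estimated correlation and 1 with fry. Cyp2a5, Dbp and Arntl were the 3 of 20 named genes that kept their call without each single library.

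In the comparison of intravenous exosomes with the DED model, interferon genes gave the list with the smallest p, and antigen presentation genes rose too. Gbp2 rose from 300.3 ± 29.3 to 898 ± 83.1 normalized counts (SD, n = 3 each; log2 fold change 1.58, SE 0.16, adjusted p = 0.000136) and Ifi47, a gene of the interferon-induced GTPases, from 294 ± 15.6 to 1072 ± 326 (1.82, SE 0.23). Psmb9, a subunit of the immunoproteasome (1.59, SE 0.20), B2m, the light chain of MHC class I (1.67, SE 0.25), and Ctss (2.04, SE 0.19, adjusted p = 0.000101) rose. Of 38 interferon genes 12 rose over all genes and 25 adjusted over the list alone, and none fell (median 1.56, adjusted p = 4.75e-26 and 0.196). Of 17 MHC class I genes 9 rose over all genes and 14 adjusted over the list alone (0.97, 7.85e-16 and 0.166). H2-D1 (1.00, SE 0.21) shares sequence with other class I genes and is uncertain. MHC class II genes rose (9 genes, 0.68, 2.32e-06 and 0.166), 1 over all genes and 3 adjusted over the list alone. The inflammasome list did not pass (16 genes, 0.19, adjusted p = 0.22), though Casp1 rose in it (2.23, SE 0.43). The interferon median was highest in intravenous 3, as was Ifi47 (1448 normalized counts against 875 and 894 in intravenous 1 and 2). With 1 library left out the interferon list ran from 1.14 (without intravenous 3) to 1.90 and MHC class I from 0.82 to 1.09.

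**Figure D3:**
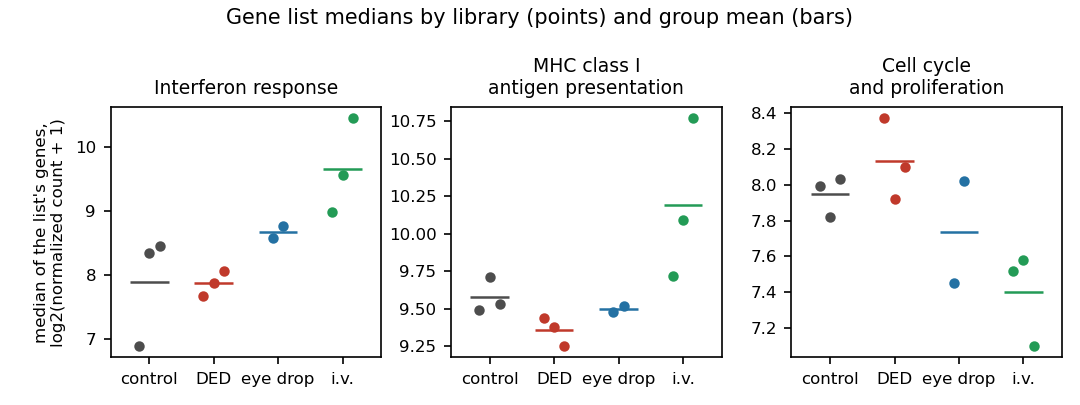
Median over the genes of the interferon, the MHC class I and the cell cycle list in each library (y axis, log2 of the normalized count plus 1), by group on the x axis. Points are libraries and bars are group means. The interferon medians of the 3 intravenous libraries were 8.98, 9.56 and 10.45, above all 8 other libraries, the highest of which was 8.77 with the eye drop.

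Clock genes moved as with the eye drop: Dbp rose by 3.14 (SE 0.30), Tef by 1.68 (SE 0.21) and Nr1d1 by 1.49 (SE 0.24), and Arntl fell by 2.18 (SE 0.22, adjusted p = 0.000136). Of 18 clock genes 7 rose and 2 fell over all genes, and 9 rose and 4 fell adjusted over the list alone. The list rose (0.60, 0.000957 and 0.411), its median being -0.02 as deposited. Cyp2a5 rose by 2.31 (SE 0.22), Bcas1 by 1.70 (SE 0.20) and Ripply3 by 1.73 (SE 0.21). Cholesterol synthesis fell (24 genes, -0.46, 1.08e-10) and also passed with an estimated correlation (adjusted p = 0.0261). Of its genes 5 fell over all genes, among them Fdps (-1.40, SE 0.18) and Idi1 (-1.21, SE 0.21). Adjusted over the list alone 12 fell and 1 rose. In the fatty acid list, which did not pass (31 genes, -0.02, adjusted p = 0.241), 5 genes fell over all genes, Scd1 (-1.51, SE 0.18) and Acaca, the enzyme that starts fatty acid synthesis (-1.07, SE 0.19), among them. Over all genes 2 rose, with 8 falling and 3 rising adjusted over the list alone. Cell cycle genes fell (40 genes, -0.81, 2.06e-21 and 0.196). Over all genes 10 fell, Top2a (-1.09, SE 0.20), Rrm2 (-1.11, SE 0.21) and Foxm1 (-1.54, SE 0.31) among them, and adjusted over the list alone 33 did. Squamous cornification fell (30 genes, -0.60, 0.000575 and 0.411). Over all genes 3 fell, Sprr1a (-3.61, SE 0.49), Ivl (-1.35, SE 0.26) and Sbsn (-2.17, SE 0.42), and 8 fell and 2 rose adjusted over the list alone. Inflammatory cytokines fell (25 genes, -0.51, 0.00151 and 0.411), 0 over all genes and 7 adjusted over the list alone. Nipal1, a magnesium transporter gene (-4.43, SE 0.53), Pigz (-2.25, SE 0.31), Las1l (-1.07, SE 0.16) and Celf3 (-2.61, SE 0.40) fell. C2cd4b was at 0 in all 3 intravenous libraries, at least 5.7-fold lower.

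Conjunctiva and goblet cell markers rose with the intravenous route (14 genes, 0.46, 0.000957 and 0.166), 4 over all genes and 6 adjusted over the list alone. The 4 were the keratins Krt4 (1.22, SE 0.22), Krt13 (0.91, SE 0.17), Krt7 (1.03, SE 0.22) and Krt8 (1.33, SE 0.30). Corneal epithelium markers did not pass (18 genes, 0.06, adjusted p = 0.433), though Krt15 (0.97, SE 0.20) and Gsto1 (0.75, SE 0.18) rose. Cytosolic ribosomal proteins (50 genes, 0.53, and -0.09 as deposited; 1.44e-17 and 0.411) and oxidative phosphorylation genes (47 genes, 0.40, and -0.22 as deposited; 1.15e-09 and 0.494) rose. None passed over all genes, and 34 and 0 adjusted over the list alone. Across genes the change fell with transcript length (rank correlation -0.32), from a median of 0.16 in the shortest to -0.10 in the longest length group. Immediate early genes rose (30 genes, 0.24, and -0.38 as deposited; 0.00535 and 0.467), Ier3 over all genes (1.00, SE 0.18), and 8 rose and 2 fell adjusted over the list alone. Glycolysis (29 genes, -0.23, 0.0492 and 0.494), osmotic stress (18 genes, -0.35, 0.0204 and 0.411) and unfolded protein genes (22 genes, -0.18, 0.0201 and 0.411) fell. Monocyte and macrophage markers rose (23 genes, 0.45, 0.27 with bounds and -0.17 as deposited; 0.0204 and 0.411). Over all genes 1, 0, 1 and 1 of their members changed in the list's direction (Pfkp -1.05, SE 0.24; Hyou1 -0.88, SE 0.20; Arg1 0.78, SE 0.18), and as many adjusted over the list alone. Skeletal muscle markers rose beside these lists (21 genes, 2.76, 3.1e-10 and 0.411), as did lens markers (23 genes, 1.29, 0.0168 and 0.791). Retina markers fell (24 genes, -1.37, 0.0024 and 0.74). None of their members passed over all genes, and 1, 0 and 0 adjusted over the list alone. The muscle gene Mb had 2080, 1309 and 59.5 normalized counts in intravenous libraries 1, 2 and 3, and 13.7, 0 and 285 in the DED libraries.

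**Figure D4:**
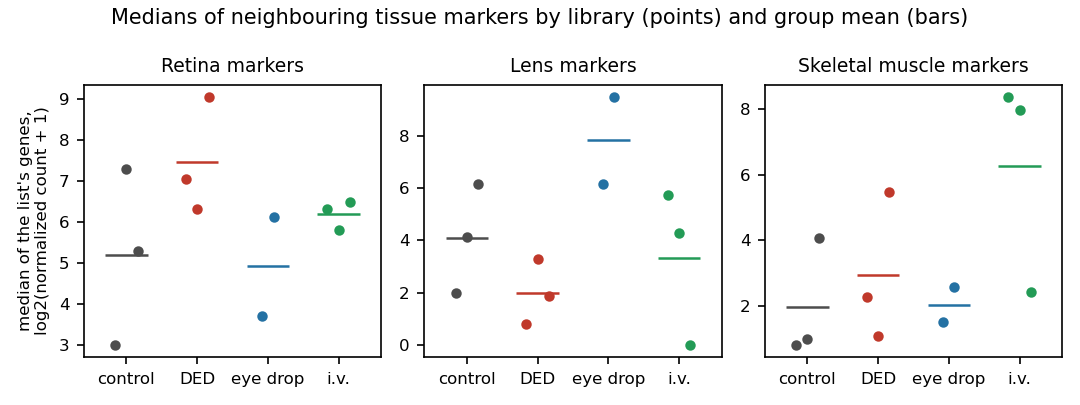
Median over the genes of the retina, lens and skeletal muscle lists in each library (y axis, log2 of the normalized count plus 1), by group on the x axis; points are libraries and bars are group means. DED 3 was highest in retina markers (9.04), eye drop 2 in lens markers (9.48) and intravenous 1 in muscle markers (8.38). Intravenous 2 followed in muscle markers (7.97), and control 3 (6.17) and eye drop 1 (6.16) in lens markers. Leaving out the 3 highest libraries therefore does not remove all of this signal.

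Against the DED model the intravenous route changed 308 genes, 204 higher and 104 lower (66.2% higher), 208 of them by at least 2-fold, where 3276 had an unadjusted p under 0.05 and chance would give 1060. With library totals 586 genes changed, 22.4% of them higher, and the median of all genes shifted to -0.25. As deposited 3739 changed, 2.4% higher, with a median of -0.58. Of the 44 lists 19 passed, 1 with an estimated correlation and 7 with fry. The number of changed genes was 66 and 85 without DED 1 and 3, 169, 191 and 1609 without intravenous 1, 2 and 3, and 46 without the 3 libraries highest in neighbouring tissue markers. It was 65 with limma without trend, 72 with only the 2 groups, 605 with the third eye drop column and 688 with the length and GC trend removed. Of 52 named genes 21 kept their call without each library: Ctss, Cyp2a5, Gbp2, Dbp, Bcas1, Ripply3, Ifi47, Psmb9, B2m, Tef, Nr1d1, Alox12e, Arntl, Nipal1, Scd1, Fdps, Pigz, Las1l, Celf3, C2cd4b and Sprr1a. Cornification was at -0.22 and -0.39 without DED 1 and 2, and conjunctiva markers at 0.24 without DED 1. Oxidative phosphorylation was at 0.26 without intravenous 2 and 0.64 without intravenous 3. Without intravenous 3 the unfolded protein response was at -0.29, osmotic stress at -0.56, macrophage markers at 0.71, lens at 2.42 and muscle at 4.43. The clock list lost its call without intravenous 3 (0.48, adjusted p = 0.0604), immediate early genes without DED 1 (0.11, adjusted p = 0.0733) or intravenous 3 (0.18, adjusted p = 0.252), retina without DED 3 (-0.36, adjusted p = 0.408). Osmotic stress lost it without intravenous 1 (-0.21, adjusted p = 0.123). Lens markers lost it without DED 1 (1.06, adjusted p = 0.0714), DED 3 (1.69, adjusted p = 0.0502), intravenous 1 (0.36, adjusted p = 0.764) or intravenous 2 (1.17, adjusted p = 0.0761). Macrophage markers lost it without DED 2 (0.11, adjusted p = 0.0889) and, with the direction turned, intravenous 1 (-0.03, adjusted p = 0.252). The unfolded protein response did so without DED 2 (-0.20, adjusted p = 0.0971) or intravenous 1 (-0.13, adjusted p = 0.29). Without the 3 libraries calls were also lost by lens (0.09, adjusted p = 0.924), retina (-0.46, adjusted p = 0.169), macrophage (0.28, adjusted p = 0.124), osmotic stress (-0.19, adjusted p = 0.182), unfolded protein (-0.15, adjusted p = 0.425) and glycolysis genes (-0.13, adjusted p = 0.26). With the trend removed they were lost by macrophage (0.34, adjusted p = 0.0777), osmotic stress (-0.28, adjusted p = 0.0921) and glycolysis genes (-0.24, adjusted p = 0.0714). As deposited they were lost by inflammatory cytokines (fell by 1.00, adjusted p = 0.0998), retina markers (-1.95, adjusted p = 0.134), oxidative phosphorylation (-0.22, adjusted p = 0.439) and immediate early genes (-0.38, adjusted p = 0.304). Immediate early genes also lost it with quantile normalization (0.15, adjusted p = 0.108), and glycolysis with 75th percentile scaling (-0.19, adjusted p = 0.0725) and the third eye drop column (-0.22, adjusted p = 0.0517). Glycolysis lost it without DED 2 (-0.19, adjusted p = 0.129), DED 3 (-0.20, adjusted p = 0.192), intravenous 1 (-0.22, adjusted p = 0.0887) or intravenous 3 (-0.08, adjusted p = 0.14).

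How far the treated corneas moved from the DED values toward control was asked of the 265 genes changed in the DED model. With the eye drop 237 of them (89.4%) differed from the DED model opposite to their DED change, and with the intravenous route 211 did (79.6%). In the direction of the DED change, the median log2 change was -0.63 and -0.48, where the DED change itself had a median of 1.30. The contrasts share the DED samples, so opposite signs also arise without a treatment effect. In 100 planned simulations without an effect the median shares were 67.23% and 69.47%, but these called a median of 2436 DED genes and so select less strongly than the real data. Simulations with the DED difference scaled by 0.6, which called a median of 214 genes, gave median shares of 76.3% and 79.1%, and 0 and 46 of 100 reached the real share. None reached the real median change, the lowest being -0.37 and -0.38. With noise that also kept the correlation between genes, 92 simulations had at least 20 DED genes (from 21 to 7803, median 290.5), with median shares of 75.2% and 77.4%. Of these, 19 and 45 reached the real share, and 3 and 15 the real median change. Of the 28 with a number of DED genes within 2 times the real one, 5 and 14 reached the share, and 0 and 5 the median change. The intravenous share was thus reached often with either noise. The eye drop share and both median changes were reached only with correlated noise, so whether they exceed what sharing the DED samples gives stays open. The same genes remained at a median of 0.74 (eye drop) and 0.86 (intravenous) from control, and 18 and 19 had moved beyond the control value. The control samples also served to pick these genes, which by itself can add distance from control. How much it added was not simulated. Among genes called in both contrasts, 24 were opposite with the eye drop, Dbp, Tef, Nr1d2, Pigz, Asb2 and Fdps among them, and 44 with the intravenous route. As many were opposite in 6 and 7 of the 92 simulations, but in none of the 28 (at most 2 and 20) or of the 100 with independent noise (at most 3 and 2). The intravenous share was 53.8% without intravenous 3, 73.3% without control 2 and 66.7% with library totals, settings for which no simulation was run.

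Both routes changed 34 genes in the same direction against the DED model, 24 higher and 10 lower, and none in opposite directions. Dbp, Tef, Cyp2a5, Gbp2, Ctss and Alox12e rose by both routes, and Arntl, Pigz, Fdps and C2cd4b fell. Independent lists of these sizes would share 0.26 and 0.07 genes, and the highest overlap in 100 simulations without an effect, where both contrasts share the DED samples, was 1. With correlated noise it was 30 in the 92 simulations and 4 in the 28 closest in number of DED genes. Across all 21203 genes, which are not independent replicates, the changes by the 2 routes correlated at 0.49, with a covariance of 0.215. With independent noise (scaled as above) none of 100 simulations reached either, with medians of 0.45 and 0.126. With correlated noise 52 of the 92 reached that correlation and 21 that covariance, and 15 and 3 of the 28 did. The overlap was 13, 18 and 13 without DED 1, 2 and 3, 4 without either eye drop library, 62 without intravenous 3, 6 with limma without trend, 22 with the replicate block, 72 with the third eye drop column and 0 without the 3 libraries highest in neighbouring tissue markers. The 3 DED samples cannot be divided into separate groups of at least 2 for the contrasts, so the part of the excess that the shared samples give was not separated.

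The routes were compared directly. Interferon genes were higher with the intravenous route than with the eye drop (38 genes, median 1.00, adjusted p = 7.78e-11 and 0.618). So were MHC class I genes (17 genes, 0.69, 6.1e-11 and 0.457) and MHC class II genes (9 genes, 0.70, 0.56 with bounds, 0.000124 and 0.457). Adjusted over the list alone 1, 11 and 3 members rose. Cell cycle genes were lower (40 genes, -0.60, 4.32e-15 and 0.457), 16 adjusted over the list alone. Ribosomal protein genes (50 genes, 0.48, and -0.21 as deposited; 9.3e-15 and 0.621), oxidative phosphorylation genes (47 genes, 0.37, and -0.32 as deposited; 7.23e-11 and 0.621) and immediate early genes (30 genes, 0.39, and -0.29 as deposited; 1.35e-05 and 0.457) were higher. Adjusted over the list alone 8, 8 and 6 rose. Across genes the change fell with transcript length (rank correlation -0.38), from a median of 0.18 in the shortest to -0.14 in the longest length group. It rose with GC content (rank correlation 0.40). Muscle (21 genes, 3.34, 3.16 with bounds, 1.84e-14 and 0.457) and retina markers (24 genes, 1.24, 0.000133 and 0.88) were higher and lens markers lower (23 genes, -3.80, 8.71e-16 and 0.457). Adjusted over the list alone 0, 1 and 2 passed. Of the 44 lists 10 passed (17 without the 3 libraries highest in neighbouring tissue markers), none with an estimated correlation and none with fry. No single gene passed over all genes with limma-trend. An unadjusted p under 0.05 was found for 1953, where chance would give 1060 on average, and the smallest adjusted p was 0.225. Whether 1953 lies beyond the spread of chance was not tested. The 5 genes with the smallest p, none of which passed, were Cyp2t4 (3.78, SE 0.63), Slc6a6 (-1.35, SE 0.23), Lctl (-2.97, SE 0.53) and the replication helicase genes Mcm4 (-1.12, SE 0.21) and Mcm2 (-1.32, SE 0.25). The count was 0 with voom, 1 with limma without trend and without eye drop 1, 2 with only these groups, 7 with the third eye drop column, 632 without intravenous 3 and 1404 as deposited. Of the last, 1.1% were higher, with the median of all genes at -0.61. Library totals gave 0 with a median of -0.17. Without intravenous 3 the medians were 0.61 for interferon, 0.62 for oxidative phosphorylation, -2.33 for lens and 5.06 for muscle. Without intravenous 2 they were 0.59 for immediate early and 0.30 for ribosomal genes, and without eye drop 2 -2.20 for lens and 2.23 for retina. The retina list lost its call without eye drop 1 (0.08, adjusted p = 0.554) and MHC class II without the 3 libraries highest in neighbouring tissue markers (0.25, adjusted p = 0.0993).

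Against control, the eye drop group differed at 1 gene, AA467197, which was higher (log2 fold change 1.94, SE 0.25, adjusted p = 0.0171), and 2249 genes had an unadjusted p under 0.05. The gene was named after its values were seen. The call was lost without control 1, control 2 or eye drop 2 (0 genes each) and without eye drop 1, where 1 other gene was called. It was also lost with limma without trend, where 1 other gene, lower, was called, without the 3 libraries highest in neighbouring tissue markers (0) and with the trend removed (0). The count was 21 with quantile normalization (38.1% higher), 12 with 75th percentile scaling, 20 with library totals (25% higher, median of all genes -0.14), and 5 as deposited. It was 9 with voom (66.7% higher), 22 without a filter, 2 with a pseudocount of 0.1, 17 when thinned, 207 with only the 2 groups and 309 with the third eye drop column.

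The intravenous group differed from control at 2405 genes, 1413 higher and 992 lower (58.8% higher), 1081 of them by at least 2-fold, and 6077 genes had an unadjusted p under 0.05. Ribosomal protein genes led: 41 of 50 rose over all genes and 48 adjusted over the list alone (median 0.88, adjusted p = 9.41e-22 and 0.39). Of 47 oxidative phosphorylation genes 29 rose over all genes and 37 adjusted over the list alone (0.85, 1.03e-18 and 0.39). Of 38 interferon genes 15 and 26 rose (1.65, 4.38e-16 and 0.39), and of 17 MHC class I genes 11 and 12 (0.98, 1.56e-09 and 0.39). Of 40 cell cycle genes 16 fell over all genes and 28 adjusted over the list alone (-0.66, 1.65e-10 and 0.39). Across genes the change fell with transcript length (rank correlation -0.53), from a median of 0.34 in the shortest to -0.36 in the longest length group. The share of higher genes was 72.2% of 2541 with 75th percentile scaling, 14.2% of 4579 with library totals (median of all genes -0.31) and 4.1% of 6517 as deposited (median -0.55). The count was 250 and 968 without control 1 and 3, 885, 1106 and 4844 without intravenous 1, 2 and 3, 188 without the 3 libraries highest in neighbouring tissue markers, 370 with limma without trend and 1262 with only the 2 groups.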

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

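The test of immune cell markers, the 4 tests of neighbouring tissue markers and the spread of their correlations were chosen after the results were seen, as were thinning, trend removal and the values as deposited. A test of the difference between the routes raised 10 lists, given here as the median log2 change of intravenous against eye drop. Interferon genes were at 1.00 (adjusted p = 7.78e-11), MHC class II at 0.70 (0.000124), MHC class I at 0.69 (6.1e-11) and cell cycle genes at -0.60 (4.32e-15). Immediate early genes were at 0.39 (1.35e-05), oxidative phosphorylation at 0.37 (7.23e-11) and ribosomal proteins at 0.48 (9.3e-15). Lens markers were at -3.80 (8.71e-16), retina at 1.24 (0.000133) and skeletal muscle at 3.34 (1.84e-14). None passed with an estimated correlation, where adjusted p ran from 0.457 to 0.88. As deposited, the immediate early, oxidative phosphorylation and ribosomal medians were -0.29, -0.32 and -0.21. The eye drop side rests on 2 libraries. Without intravenous 3, the library highest in interferon genes, the interferon difference was 0.61 (adjusted p = 0.00219). The retina difference was 0.08 without eye drop 1 (adjusted p = 0.554), and MHC class II was at 0.25 without the 3 libraries highest in neighbouring tissue markers (adjusted p = 0.0993).

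Interferon and MHC class I genes were higher with the intravenous route than in the DED model, within a broad difference of the intravenous libraries, which also had the lowest totals. A trend with transcript length and GC content as the whole cause is argued against by the interferon median, 1.56 before and 1.58 after trend removal, and by the 2118 genes then changed against control, but only 1243 of these were among the 2405 called before, so many single calls depend on the trend. Lower depth is argued against by 2222 genes with all libraries thinned to the lowest total, 2139 of them among the 2405. More immune cells cannot be told apart from other causes. Of 55 immune cell markers 35 were higher, with a median of 0.27 (95% interval over genes 0.01 to 0.51), where the interferon median was 1.56. At least 10 counts in every library were found for 18 of them, with a median of 0.10. The 10 macrophage markers among these gave 0.32 (95% interval -0.22 to 0.88), but the other 3 lists held at most 3 each. A response to the intravenous route stays open as an untested hypothesis, and an infection of these mice, also untested, may raise the same genes.

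Markers of neighbouring tissues differed between libraries of the same group. Carry-over in dissection is consistent with the markers varying together within groups, with a mean pairwise correlation of 0.77 (jackknife SE 0.09) for 24 retina, 0.81 (SE 0.03) for 23 lens and 0.81 (SE 0.04) for 21 muscle markers, each above 100% of 1000 random lists. At least 10 counts in every library were found for 9, 1 and 2 of them, and no other list holds any; Cryaa reached 10206 normalized counts in eye drop 2 and Mb 2080 in intravenous 1. An unequal share of the inner corneal layers cannot be told apart from other causes, since 13 corneal endothelium markers gave 0.20 with an SE of 0.18 (above 98.7% of random lists), 10 of them at 10 or more counts in every library and 4 in another list. No biological explanation was tested, as the labels name no treatment of these tissues.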

How the results depend on the processing

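Library totals, values as deposited, voom, thinning, a filter of 10 counts, trend removal, the third eye drop column and leaving out the 3 libraries highest in retina, lens and muscle markers were chosen after the data were seen. Counts are given in the order DED model against control (265), eye drop and intravenous against the DED model (41, 308), intravenous against eye drop (0), eye drop and intravenous against control (1, 2405) and any of the 4 groups (956), and the movement (89.4% and 79.6%) and the overlap (34) as in the report. The cause of a change was not tested unless given.

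With limma without trend and robust estimation the counts were 60, 6, 65, 1, 1 (not the gene called before), 370 and 33, and the overlap 6. With the third eye drop column, whose values add no spread, they were 594, 115, 605, 7, 309, 3429 and 2246, the overlap 72 and the intravenous movement 73.7%. With only the 2 groups the 1st and the 3rd to 6th were 662, 72, 2, 207 and 1262. Without the 3 libraries, which leaves fewer samples, they were 63, 0, 46, 0, 0, 188 and 84, the overlap 0, the intravenous movement 92.1% and the list calls between the routes 17. With library totals the intravenous counts were 586 and 4579, eye drop against control 20, any group 2101 and the intravenous movement 66.7%. As deposited the 3rd to 7th counts were 3739, 1404, 5, 6517 and 5137. Trend removal gave 688 for intravenous against the DED model and 0 for eye drop against control, which also had 21 (quantile), 12 (75th percentile), 22 (no filter), 2 (pseudocount 0.1), 9 (voom) and 17 (thinned). A log2 fold change of at least 1 gave 1081 for intravenous against control by its construction, and movement of 93.7% and 86.4%.

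The replicate number as a block gave 212, 26, 358, 0, 1, 2463 and 1027, the overlap 22 and movement of 88.2% and 81.1%. Whether the numbers pair the samples was not settled. Of 15 same-number pairs 3 correlated above 0.1 over 11808 genes (from -0.26 to 0.44), and 5 of 11 samples went best with their own number. The highest correlation of all pairs between groups, 0.44, was between control 1 and DED 1.

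Leaving out each library gave from 51 to 303 genes, from 4 to 21, from 66 to 1609, from 0 to 632, from 0 to 1, from 250 to 4844 and from 210 to 3749 in the same order, movement from 78% to 97.3% and from 53.8% to 93%, and an overlap from 4 to 62. List calls, 21, 11, 19, 10, 21 and 24 in the order of the 6 comparisons, ran from 21 to 24, 11 to 21, 15 to 23, 11 to 14, 12 to 24 and 20 to 24. They were 0, 1, 1, 0, 0 and 0 with an estimated correlation and 11, 1, 7, 0, 0 and 11 with fry, which asks another question.

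Called list medians turned sign as follows. As deposited, where the median of all genes itself shifted, intravenous against the DED model gave immediate early -0.38, oxidative phosphorylation -0.22, ribosomal -0.09, clock -0.02 and macrophage -0.17, intravenous against eye drop gave -0.29, -0.32 and -0.21 for the first 3, and intravenous against control gave inflammatory -0.14, MHC class II -0.02, NRF2 -0.32 and immediate early -0.43. With library totals the last 2 gave 0 and -0.12. With 1 library left out, macrophage markers in intravenous against the DED model ran from -0.03 (without intravenous 1) to 0.71. Retina markers in intravenous against control ran from -0.06 (without control 1) to 1.78, and complement in eye drop against control from -0.01 (without eye drop 1) to 1.21.

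Lists without a call also turned sign and gained one. As deposited these were red blood cell (-0.21) and tight junction genes (-0.62, from 0) in intravenous against the DED model, and NRF2 (-0.64) and neurotrophic genes (-0.37) between the routes. In intravenous against control they were metalloproteinase (-0.21), fatty acid (-0.65), T, NK and B cell (-0.14) and skin genes (-0.10). Quantile normalization gave -0.20 for the tight junctions. Without the 3 libraries complement, collagens and keratocyte markers were at 0.76, 0.73 and 0.91 in eye drop against the DED model and at -0.57, -0.86 and -0.55 between the routes, and cell cycle genes at -0.29 in eye drop against control. With 1 library left out, in eye drop against the DED model, complement ran from -0.33 to 0.56, collagens from -1.02 to 0.54 and keratocyte markers from -0.65 to 0.50. Collagens between the routes ran from -0.72 to 0.83 and cell cycle genes in eye drop against control from -0.30 to 0.27. These 5 turned without eye drop 2. In intravenous against the DED model neurotrophic genes ran from -0.63 (without DED 1) to 0.12 and tight junctions from -0.23 (without intravenous 3) to 0.08. Over all lists and comparisons, leaving out 1 library left 1302 results with or without a call as before, 64 lost and 76 gained a call, and 10 turned.

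No called named gene turned direction under the alternatives run. Of 54, 20 and 52 called named genes, 23, 3 and 21 kept their call without each library, 18, 3 and 19 with limma without trend, and 26, 0 and 22 without the 3 libraries. Of these, 50, 19 and 42 kept it with quantile normalization, 47, 19 and 47 with library totals, 39, 16 and 37 as deposited, and 51, 19 and 47 with voom. Of the called lists 17 of 21, 8 of 11, 11 of 19, 9 of 10, 10 of 21 and 13 of 24 kept their call without each library.

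Depth limits low genes: Nfil3 and C2cd4b averaged 20.9 and 17.1 normalized counts in the DED model, and the counts of 0 of both with the eye drop, and of C2cd4b with the intravenous route, allow up to 3 counts per library. In simulations 34.2% to 49.5% of 2-fold changes were recovered. These changed only genes with a mean of at least 10 normalized counts, so recovery of lower genes was not measured.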

Other observations

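The clock tests below were chosen after the results were seen, as were library totals, trend removal, the values as deposited and leaving out the 3 libraries highest in neighbouring tissue markers; the counts over other splits of the samples were planned. Between the DED model and control, the following lists did not pass. Interferon genes had a median of -0.01 (38 genes, mean 0.04, adjusted p = 0.662), with 1 member, Gbp2, lower over all genes (-0.84, SE 0.16). Without control 1 the list fell to -0.50 (adjusted p = 1.4e-05). MHC class I and II genes gave -0.02 (0.879) and -0.19 (0.198), and -0.16 (0.0435) and -0.27 (0.045) without control 1. In the tight junction list (-0.03, 0.473) Cldn8, a claudin gene, fell (-1.79, SE 0.40). In the retinoid and PAX6-linked list (0.27, 0.28) Cyp26b1, which degrades retinoic acid, fell (-1.26, SE 0.22) and Crabp2, which binds it, rose (2.16, SE 0.44). Mucins gave 0.43 (0.31 with genes at 0 in a group set to their bound, 0.0881), 0.50 (0.0391) without control 1 and 0.42 (0.0404) without DED 3. Complement gave 0.32 (0.0881), 0.56 (0.0394) without control 2 and 0.52 (0.0328) without DED 1. Cell cycle genes gave 0.10 (0.175), 0.18 (0.035) without control 3 and 0.21 (0.0214) without DED 2. In the inflammasome list (0.02, mean -0.06, 0.877 with a downward test) the gasdermin gene Gsdma (2.06, SE 0.43) and Pycard (0.92, SE 0.20) rose. Immediate early genes gave 0.03 (0.996 with a downward test), where Hsph1 rose (0.89, SE 0.20). NRF2 genes gave 0.24 (0.0889), p53 targets 0.21 (0.879), osmotic stress genes 0.16 (0.879), corneal epithelium markers 0.20 (0.298) and conjunctiva markers 0.14 (0.63). Macrophage markers gave 0.32 (0.178), lymphocyte markers 0.37 (0.21 with bounds, 0.4), dendritic cell markers 0.01 (0.987 with a downward test) and skin markers 0.56 (0.263). Red blood cell markers gave -0.59 (0.113), -1.36 (0.0275) without control 3 and -1.25 (0.0142) without DED 3. Lacrimal gland markers gave 0.56 (0.32 with bounds, 0.0898) and 1.10 (0.0412) without DED 1. Muscle markers gave 0.91 (0.64 with bounds, 0.519) and 1.58 (0.0358) without control 3.

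Against control, 21 lists passed with the eye drop and 24 with the intravenous route. None did with an estimated correlation, where adjusted p ran from 0.339 to 0.464 and from 0.39 to 0.632. With the eye drop, 10 lists kept their call without each library. Of these, interferon (0.66, adjusted p = 7.49e-08), inflammatory cytokine (0.52, 0.000435), antimicrobial peptide (0.98, 1.87e-05), matrix metalloproteinase (0.98, 0.0032) and NRF2 genes (0.31, 0.00134) rose. So did oxidative phosphorylation (0.35, 1.52e-10), ribosomal (0.39, 9.01e-10), neutrophil (0.98, 0.00377) and lens genes (3.49, 5.9e-12). Across genes the change with the eye drop against control fell with transcript length (rank correlation -0.41). Its median was 0.17 in the shortest and -0.20 in the longest length group. WNT and NOTCH genes fell (-0.44, 2.53e-05), 9 of 28 adjusted over the list alone. Without control 1 interferon was at 0.21, NRF2 at 0.20, oxidative phosphorylation at 0.22, neutrophil at 0.61 and lens markers at 2.30. Without eye drop 1 and 2 lens markers were at 5.43 and 1.77, and interferon was at 0.42 without eye drop 2. Without eye drop 1 complement turned from 0.64 (0.0146) to -0.01. Calls were then also lost by collagens (1.03, 1.11e-07, to 0.20), keratocyte (1.08, 0.00019, to 0.24), endothelium (1.10, 0.00419, to 0.42) and vessel markers (0.87, 0.0105, to 0.43). The same held for macrophage markers (0.71, 0.57 with bounds, 0.00661, to 0.29), TGF-beta genes (0.85, 0.00351, to 0.54), conjunctiva markers (0.38, 0.0137, to 0.37) and cornification (0.31, 0.0414, to 0.29). Iris markers lost theirs without eye drop 2 (0.66, 0.61 with bounds, 0.00377, to 0.37), and were at 1.02 without control 2 and 1.24 without eye drop 1. Without eye drop 2 complement was at 1.21, collagens at 1.76, endothelium at 2.39 and vessel markers at 1.37. Without control 1 TGF-beta genes were at 0.56 and keratocyte markers at 0.69. Without control 1 MHC class I (0.36, 0.00923, to 0.08), complement (0.47), cornification (0.21) and conjunctiva (0.30) lost theirs. Cornification also lost its call with the replicate block (0.33, 0.0664), 75th percentile scaling (0.37, 0.0911) and the trend removed (0.32, 0.119), conjunctiva with quantile normalization (0.12, 0.131) and iris without the 3 libraries (0.38, 0.223).

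In the intravenous group against control, antimicrobial peptides (1.21, adjusted p = 0.000127), MHC class II (0.60, 0.00442, but -0.02 as deposited), collagens (0.94, 2.08e-05) and conjunctiva markers (0.71, 0.00216) rose. So did keratocyte (1.10, 0.00106), macrophage (0.84, 0.00442), iris (1.08, 0.000751) and muscle markers (3.67, 7.91e-08). These 8 kept their call without each library, with iris markers at 1.71 without control 2. Retina markers were at 1.78 and immediate early genes at 0.13 without control 2, and the latter at 0.40 without control 3. Neutrophil markers were at 1.23 without control 3 or intravenous 1 and 1.14 without intravenous 3, where the clock was at -0.47. The inflammatory cytokine call (0.46, 0.38 with bounds, 0.00786) was lost without control 2 (0.40) or intravenous 3 (0.19), and the median was -0.14 as deposited. The cornification call (0.59, 0.0338) was lost without control 1 (0.49) or intravenous 3 (0.74). The immediate early call (0.21, 0.038) was lost without control 1 (0.16) or intravenous 3 (0.08), and the median was -0.12 with library totals and -0.43 as deposited. The NRF2 call (0.34, 0.0191) was lost without intravenous 2 (0.28), and the median was 0 with library totals and -0.32 as deposited. Complement (0.91, 0.0344) lost its call without control 1 (0.59), intravenous 1 (0.63) or intravenous 2 (0.88), and vessel markers (1.17, 0.0179) without intravenous 1 (0.74). The clock (-0.22, 0.0437) lost it without control 2 (-0.22), intravenous 1 (-0.17) or intravenous 2 (-0.13). Endothelium markers (1.37, 0.0308) lost it without control 1 (1.08) or intravenous 3 (0.89), and neutrophil markers (0.72, 0.0308) without control 1 (0.46) or intravenous 2 (0.71). Lacrimal markers (1.01, 0.0374) lost it without control 2 (1.09) or intravenous 1, 2 or 3 (0.60, 0.51 and 0.85). Retina markers (0.85, 0.0359) turned without control 1 (-0.06) and lost the call without intravenous 1 (0.68) or 3 (0.75). Other settings ended further calls. With the trend removed these were cornification (0.40, 0.157), NRF2 (0.14, 0.308), immediate early (0.10, 0.0942), clock (-0.13, 0.217), neutrophil (0.54, 0.0806), retina (0.77, 0.0532) and lacrimal (0.95, 0.0833). With 75th percentile scaling they were complement (1.00, 0.0548), cornification (0.69, 0.0601), clock (-0.12, 0.0609), neutrophil (0.75, 0.0548), retina (0.94, 0.0623) and lacrimal (1.10, 0.0558). With quantile normalization they were NRF2 (0.23, 0.159), immediate early (0.13, 0.286), endothelium (0.92, 0.0913) and lacrimal (0.39, 0.0913). Without the 3 libraries they were complement (0.62, 0.0766), clock (-0.17, 0.258), vessel (0.74, 0.0561) and lacrimal (0.59, 0.0603).

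Clock genes differed between the DED model and the other groups: 10 genes of the output arm had a median change of -1.75 against control (10 lower, from -2.82 to -0.58), and 5 genes of the opposing arm 1.40 (4 higher). Fewer corneal cells as the cause is argued against by the corneal epithelium markers, at 0.20, and a general loss of clock gene expression by the opposing arm, at 1.40. The time of day of collection cannot be told apart from an effect of the model, because the labels give no time: the output arm minus the opposing arm was -0.15, 0.37 and 0.17 in the DED libraries and at least 2.35 in each of the 8 others. Against the DED model, the output arm was at 1.67 and 1.42 in the treated groups and the opposing arm at -1.19 and -1.03, so a collection time that set the DED mice apart may account for part of what the routes share. A change of the clock in dry eye and its move back with exosomes is the biological hypothesis. Recorded collection times would test it against the time of day. Without mice given the drop or the injection alone, they would not separate the exosomes from the way they were given. The treated groups did not match control at every clock gene. Arntl averaged 68 (eye drop) and 73.6 (intravenous) normalized counts against 125.6 in control, and Per3 725 and 589 against 1070.

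For the DED model against control, 1 of the 10 splits of the 6 samples, the real one, gave 265 genes, and the highest other gave 7. For the intravenous route against the DED model 1 of 10 gave 308, with 39 as the highest other, and against control 1 of 10 gave 2405, with 0 as the highest other. The 10 splits are too few for a share under 0.05. The difference between any of the 4 groups was set against 100 groupings of the 11 samples, the real one included. Only the real one gave 956 genes, and the highest other gave 97. So high a count was thus rare under random grouping. The groupings were run with the main settings alone. They cannot tell a treatment effect from anything else that may have differed between groups, such as the time of day of collection.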
